A study of Mus musculus with 12 samples.

How the data were processed

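Kidneys of male C57BL/6 mice were profiled by bulk RNA sequencing in 12 libraries, 3 in each of 4 groups. Normal mice received neither cisplatin nor vesicles, and are listed with 0 intravenous doses and no day of collection. The 3 other groups received cisplatin, a platinum drug that crosslinks DNA and damages the renal tubule, by intraperitoneal injection at 9 mg/kg once a week for 5 cycles. They then received 5 intravenous injections 3 days apart of phosphate-buffered saline (PBS group) or of extracellular vesicles from iMSC, as the labels abbreviate the source cells, at 200 µg (EV200 group) or 400 µg (EV400 group). Kidneys of the cisplatin groups were taken 3 days after the last injection, per the labels' protocols. The labels give 1 batch for all libraries, 3 biological replicates per group with no statement that each came from a separate mouse, and no hour of collection. P-values therefore measure only the spread between these samples.

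The libraries were made with a strand-specific poly(A) kit and sequenced as paired reads of 101 bases, per the labels' protocols. FastQC 0.11.7, Trimmomatic 0.38, HISAT2 2.1.0 and StringTie 2.1.3b are named, with mouse builds GRCm38 and mm10, per the submitters' processing notes. The counter, its strand setting and the annotation version are not given in the sources used here. The authors deposited 1 table of whole-number read counts per gene for 45777 genes, which was used as it stands. The 24 further per-sample columns of FPKM and TPM values in that table were not used. Total counts per library ranged from 46.6 to 62.1 M, and 17340 genes had a count of 0 in every library. Of the gene identifiers, 45679 matched a RefSeq table of GRCm38.p6, from which coordinates were taken. Exon overlaps were looked up in GENCODE vM21.

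Counts were tested in R 4.3.3 with the quasi-likelihood test of edgeR 4.0.16. All 12 libraries entered 1 fit with TMM scaling factors, the default expression filter by group and 8 residual degrees of freedom, which left 18730 genes. A gene was called where its Benjamini-Hochberg adjusted p was under 0.05. Each cisplatin group was compared with normal, each vesicle dose with PBS, the doses with each other, and the mean of both doses with PBS. A joint test asked for any difference among the 4 groups. Levels are CPM, counts scaled to the library size times its TMM factor, as mean ± SD over 3 libraries. The standard error (SE) of a log2 fold change is its absolute value divided by the square root of the F statistic.

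A set of 38 gene lists covering fibrosis, tubular injury, kidney cell types, immune cells, stress responses, metabolism, the circadian clock and other tissues, with 704 genes, was tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01. The test was repeated with a correlation estimated from the data. It was also run with fry, which asks whether the genes of a list move one way and makes no comparison with other genes. Of the list genes, 7 were missing from the table and 645 passed the expression filter.

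The groups, the tests, the lists, 12 injury and fibrosis genes reported in every comparison, and the rule for other named genes were fixed before the data were examined. That rule took up to 8 genes per direction with the largest change, or 4 for the doses against normal or each other. These had to be called, to have a gene symbol other than a provisional one, to average at least 5 CPM in the higher group and to show no overlap of the libraries of both groups. It added up to 3 members with the smallest p of each list that passed or had a called member. It also added the genes with the largest changes among those called in opposite directions by cisplatin and a vesicle dose. A gene named outside that rule is said to be so.

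Alternatives listed in advance were the scaling factors of DESeq2, other filters on low counts, DESeq2 1.42.0, limma-voom with quality weights, the replicate number as a block, a fit of the compared groups alone, a minimum log2 fold change of 1 and leaving out each library. A clock score as a covariate, summed counts of a pair of gene models, the omission of a pair of libraries, and fry were chosen after seeing the data. The clock score is the mean standardized log2 CPM of Dbp, Tef, Per2, Per3 and Ciart minus that of Arntl, Npas2 and Clock. Per2 and Clock lie outside the naming rule. On simulated counts with 200 changed genes per run in 5 runs, the test recovered 56.7% of 2-fold and 80.6% of 4-fold changes for PBS against normal among a median of 18400 genes. It recovered 62.8% and 83.3% for EV200 against PBS among 18363 genes, and 60.8% and 80.6% for EV400 against PBS among 18407 genes. False calls per run averaged 10.4, 6.8 and 5.6, respectively. The simulation drew genes independently, with the same dispersion for a gene in every group. It therefore lacks differences of whole libraries within a group, which move many genes together. The recovered shares and false calls apply to such counts and may not hold for the real libraries. Reads without molecular identifiers are not independent molecules, so limits from counts cover counting error only.

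Reads from overlapping or near-identical genes can be divided between them in ways the table does not show. In GENCODE vM21, exons of Nat8f5 and Nat8f6 overlap on the same strand, as do those of Foxp3 and Flicr, and those of Dbp overlap an antisense gene. Srd5a2 and Col3a1 overlap other genes on the same strand. Banp, Arntl, Tef, Ltbp2, Prom1, Umod, Cry2, Hmgcs1, Alas2, Fn1, Cdkn1a, Vcam1, Coro2a, Tnc, Krt7, Cldn19 and Hspa1a overlap antisense genes as well. These values, with those of the paralogs Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Cyp4a12a and Cyp4a12b, and Hspa1a and Hspa1b, are uncertain to that extent.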

Results

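Gene expression was measured in 12 mouse kidney libraries, 3 each from normal mice, cisplatin-treated mice given PBS, and cisplatin-treated mice given 200 or 400 µg of extracellular vesicles. The series title names cisplatin-induced tubulointerstitial fibrosis, the deposition of matrix between tubules, and its attenuation by these vesicles as the subject. Total counts per library averaged 51.57 ± 1.187 M in the normal group, 55.11 ± 7.86 M in the PBS group, 56.54 ± 4.65 M in the EV200 group and 48.11 ± 0.2933 M in the EV400 group (SD, n = 3). The 10 most abundant genes held 16.65 to 21.8% of the counts, with the mitochondrial gene COX1 highest in each library. The first principal component carried 43.4% of the variance of log2 CPM, with normal libraries at -47.9 to -39, PBS at 15.4 to 83.4, EV200 at -18.7 to 60.5 and EV400 at -52.1 to 7.9. Library PBS 3 held adipocyte transcripts, with the adipokine gene Adipoq at 7.67 CPM against 0 to 0.12 CPM in the 11 other libraries. COX1 and Adipoq lie outside the naming rule and were chosen after their values were seen. Library EV200 3 lay at 60.5 on the first component, while EV200 1 and EV200 2 lay at -18.7 and -8.6. Library EV400 3 stood apart as well, at -52.1 on the first and -51.5 on the second component against 1.1 and 7.9, and -15.7 and -1.3, in EV400 1 and EV400 2.

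The comparison of PBS with normal asks how kidneys differed after the cisplatin course and the PBS injections. Normal mice are listed without intravenous injections, so an effect of cisplatin cannot be told apart from that of the injections. Changes ascribed to cisplatin below are changes of PBS against normal. By camera, lists of macrophage, matrix, tubular injury and loop of Henle genes were higher after cisplatin, and proximal tubule, androgen-responsive and erythroid lists were lower, but none of the 20 lists called was called with an estimated correlation (smallest adjusted p 0.302). Lcn2, which encodes the secreted tubular injury marker NGAL (chromosome 2, 32384637 to 32387739, GRCm38), rose 22.9-fold from 0.5401 ± 0.229 to 12.37 ± 8.89 CPM (SD, n = 3). Tnc, encoding the matrix glycoprotein tenascin C (chromosome 4, 63959785 to 64047015), rose 15.9-fold to 22.2 ± 17.4 CPM. Prom1, encoding the progenitor surface protein CD133 (chromosome 5, 43993621 to 44102047), rose 2.35-fold to 103.3 ± 28 CPM. Srd5a2, encoding the steroid 5-alpha-reductase type that forms dihydrotestosterone (chromosome 17, 74014891 to 74047860), fell from 57.34 ± 9.07 to 23.71 ± 1.99 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, their adjusted p were 0.0471, 0.0405, 0.0321 and 0.0174.

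The test called 514 of 18730 genes, 345 higher and 169 lower in PBS, with 5581 genes at an unadjusted p under 0.05. DESeq2 called 2855 and limma-voom 6164, and these included 509 and 512 of the 514. Limma-voom weighted PBS 3 by 3.47, against 0.666 for PBS 1 and 0.163 for PBS 2, so its count leans on PBS 3. Fitting only the groups compared gave 1449, a filter-free fit 299, and a clock score as covariate, chosen after seeing the data, 0. The count depended on single libraries: it was 0 without normal 1, normal 2 or normal 3, 2277 without PBS 1, 1 without PBS 2 and 79 without PBS 3, so each call named in this comparison rests on all 3 normal libraries. Of the largest risers, Gpnmb and Fcrls, both genes of phagocytic macrophages, reached 17.43 ± 7.95 and 6.255 ± 3.81 CPM from normal levels of 0.0479 and 0.01369 CPM at which most libraries held no count. Ltbp2, encoding a microfibril-associated matrix protein, reached 10.48 ± 6.47 from 0.1008 CPM, and Lyz1, encoding a lysozyme of Paneth and myeloid cells, reached 6.881 ± 3.08 from 0.1555 CPM. Gabrp, Gsdmc2 and Gxylt2 rose as well, by 7.65, 5.50 and 4.58 on the log2 scale. The matrix protease gene Mmp3 averaged 1.778 ± 1.37 CPM in PBS and 0 CPM in normal. The largest falls by log2 fold change were in Synpr, encoding a synaptic vesicle protein, at -3.65, the clock gene Ciart at -1.97, and Angptl7, encoding a secreted angiopoietin-like protein, at -1.52. Dbp, a clock output transcription factor gene, changed by -1.48, and the N-acetyltransferase genes Nat8f6 and Nat8f5 by -1.29 and -1.24. The endocytic kinase gene Aak1 had -1.44, but summed with the provisional model Gm38495, an older name of Aak1 in the RefSeq table, it had -0.14 and was not called (adjusted p 0.293 by edgeR with Benjamini-Hochberg adjustment).

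Of the 12 injury and fibrosis genes chosen in advance, 1 passed over all genes, Lcn2, and 12 passed when adjusted over the list alone. Lcn2 missed the threshold without normal 1, normal 2, normal 3, PBS 2 or PBS 3, with Benjamini-Hochberg adjusted p of 0.138, 0.161, 0.148, 0.152 and 0.0665 by edgeR. DESeq2 called 9 and limma-voom 12 of them, but DESeq2 gave Lcn2, at a log2 fold change of 4.53, no adjusted p, so that gene was left out of its adjustment. In 11 of the 12, each PBS library lay above each normal library, and chance parts 3 libraries from 3, in one direction or the other, for 10% of genes. Havcr1, encoding the proximal tubule injury marker KIM-1 (chromosome 11, 46739822 to 46779578), averaged 9.567 ± 5.71 CPM in PBS and 1.53 ± 0.476 CPM in normal. Its log2 fold change was 2.64 (SE 0.87), with a Benjamini-Hochberg adjusted p of 0.0836 by edgeR. Col1a1, the collagen I chain gene (chromosome 11, 94936224 to 94953042), had 2.12 (SE 0.58) and an adjusted p of 0.0592. Log2 fold changes were 2.15 for collagen III (Col3a1), 1.44 for fibronectin (Fn1), 1.03 for smooth muscle actin (Acta2), 0.47 for Tgfb1, 2.62 for the adhesion molecule Vcam1 and 4.24 for the injury keratin Krt20. They were 2.60 for the monocyte chemokine Ccl2, 1.34 for the cell cycle inhibitor Cdkn1a and 0.31 for uromodulin (Umod). The adjusted p of these genes by edgeR with Benjamini-Hochberg adjustment lay between 0.0587 and 0.141.

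**Figure D1:**
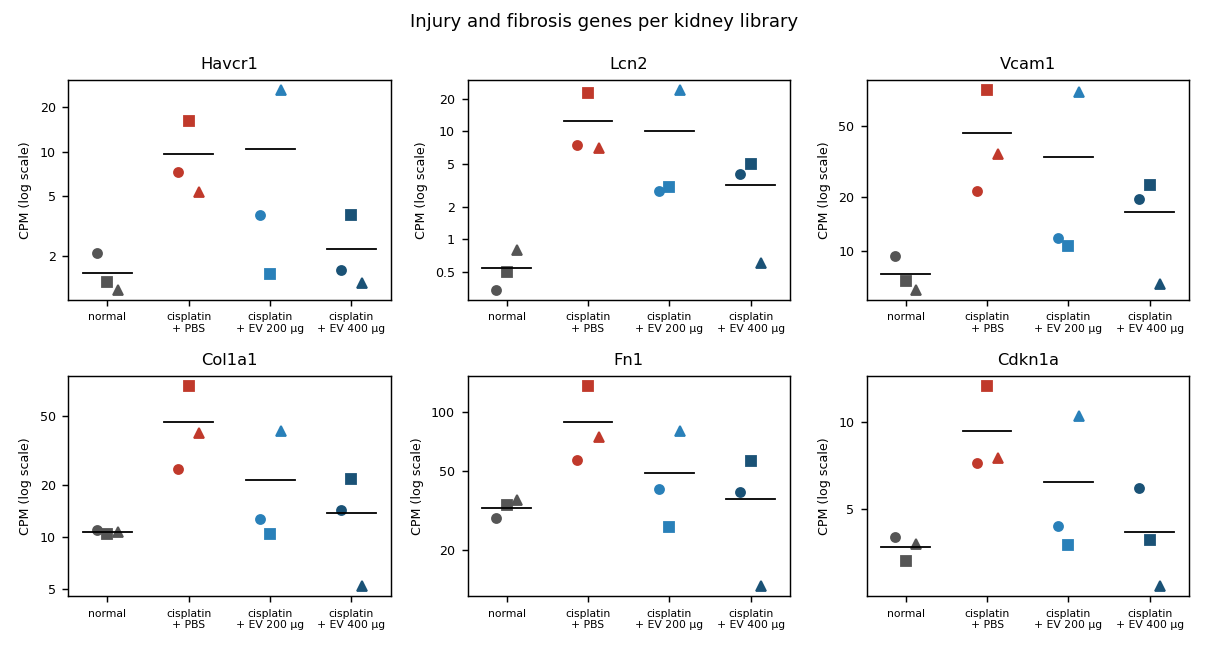
CPM on a log axis for 6 injury and fibrosis genes in the 12 kidney libraries. Each point is a library, its shape names the replicate number, and the black line is the mean of the group. For Havcr1 the PBS libraries sit between 5.36 and 16.1 CPM and the normal libraries between 1.18 and 2.07, while EV200 3 alone stands at 26 CPM.

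Of the 38 gene lists, camera called 20 in PBS against normal, 13 up and 7 down. Fry called 11. Among the 645 list genes tested, 66 passed edgeR's test over all genes and 346 had an unadjusted p under 0.05. In each list called in any comparison, the mean, the median and the test had the same sign.

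The list of macrophages and dendritic cells had 23 measured members with a mean log2 fold change of 2.33. Over all genes 6 members rose, and 22 did when adjusted over the list alone, among them Ctss, encoding the lysosomal protease cathepsin S, from 13.84 ± 3.81 to 67.74 ± 26.4 CPM, and Ms4a7 at 2.75. Its camera adjusted p was 1.1e-15 after Benjamini-Hochberg adjustment, and adjusted p = 0.339 with an estimated correlation. In the list of T and natural killer cells, 2 of 18 rose over all genes and 10 adjusted over the list alone, including Cd3d at 1.97 and the regulatory T cell factor Foxp3 at 4.91 (adjusted p = 0.339 with an estimated correlation). In the fibrosis list, 5 of 30 members rose and 22 did adjusted over the list alone, among them Tnc, periostin (Postn, 2.17) and lumican (Lum, 2.93), and the list's median was 1.44 (adjusted p = 0.339 with an estimated correlation). The TGF-beta list had 2 of 22 up, and 6 adjusted over the list alone, with Inhba, encoding the activin A subunit, at 3.50 (adjusted p = 0.411 with an estimated correlation). The tubular injury list had 9 of 29 up over all genes, and 24 up and 3 down adjusted over the list alone, with Prom1, keratin 7 (Krt7, 0.51) and the secreted chaperone clusterin (Clu, 0.81) among them (adjusted p = 0.339 with an estimated correlation).

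In the proximal tubule list, 4 of 39 members fell and 27 did adjusted over the list alone, with a mean of -0.40 (adjusted p = 0.339 with an estimated correlation). Cyp2e1, a cytochrome P450 (chromosome 7, 140763819 to 140774990), fell from 2185 ± 70.9 to 1437 ± 234 CPM. The basolateral glucose transporter gene Slc2a2 had -0.55 and the organic anion transporter gene Slc22a30 -0.53. The loop of Henle list had 6 of 12 members up, and 9 adjusted over the list alone, including Slc12a1, encoding the NKCC2 cotransporter, from 656 ± 68.4 to 1046 ± 142 CPM, the potassium channel gene Kcnj1 at 0.47 and the tight junction gene Cldn19 at 1.01 (adjusted p = 0.302 with an estimated correlation). In the androgen-responsive list, 3 of 14 fell and 11 did adjusted over the list alone, with the fatty acid hydroxylase genes Cyp4a12a at -1.08 and Cyp4a12b at -0.82 and the organic anion transporter gene Slco1a1 at -0.64 (adjusted p = 0.302 with an estimated correlation). Oxidative phosphorylation had a mean of -0.32 over 27 genes, and it was called with no member past the test either over all genes or adjusted over the list alone, with a mean of -0.14 without PBS 2 (adjusted p = 0.411 with an estimated correlation). The erythroid list had 5 of 8 down, and 6 down and 1 up adjusted over the list alone, with the heme synthesis gene Alas2 at -1.19 and the globin genes Hbb-bt at -1.19 and Hba-a2 at -1.23 (adjusted p = 0.302 with an estimated correlation).

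Urothelial genes were higher in PBS as well: 3 of 12 passed over all genes and 10 adjusted over the list alone, among them Upk3b, encoding uroplakin 3B, at 2.70 and Psca at 4.30 (adjusted p = 0.339 with an estimated correlation). Across libraries the urothelium score did not always follow the tubular injury score. EV200 1 and EV200 2 had -2.49 and 0.8 at injury scores of 4.16 and 4.12, though EV200 3 was highest in both, at 1.48 and 5.51. Gsdmc2 lay at 0.26, 5.06 and 5.43 CPM in these libraries. The senescence list was not called by camera (Benjamini-Hochberg adjusted p 0.101), but in it Cdkn2b, the gene of the cell cycle inhibitor p15, rose 9.78-fold and Igfbp3 fell to 128.4 from 232 CPM. The heat shock genes Hspa1a and Hspa1b rose by 0.76 and 0.89. In the p53 list Btg2 rose by 0.85, and that list was not called (Benjamini-Hochberg adjusted p 0.0765 by camera). The adipose list had a mean of 2.88, a median of 0.48 and a camera test pointing down (Benjamini-Hochberg adjusted p 0.994), with library PBS 3 at 5.83 and the other PBS libraries at 3.2 and 2.24 mean log2 CPM.

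**Figure D2:**
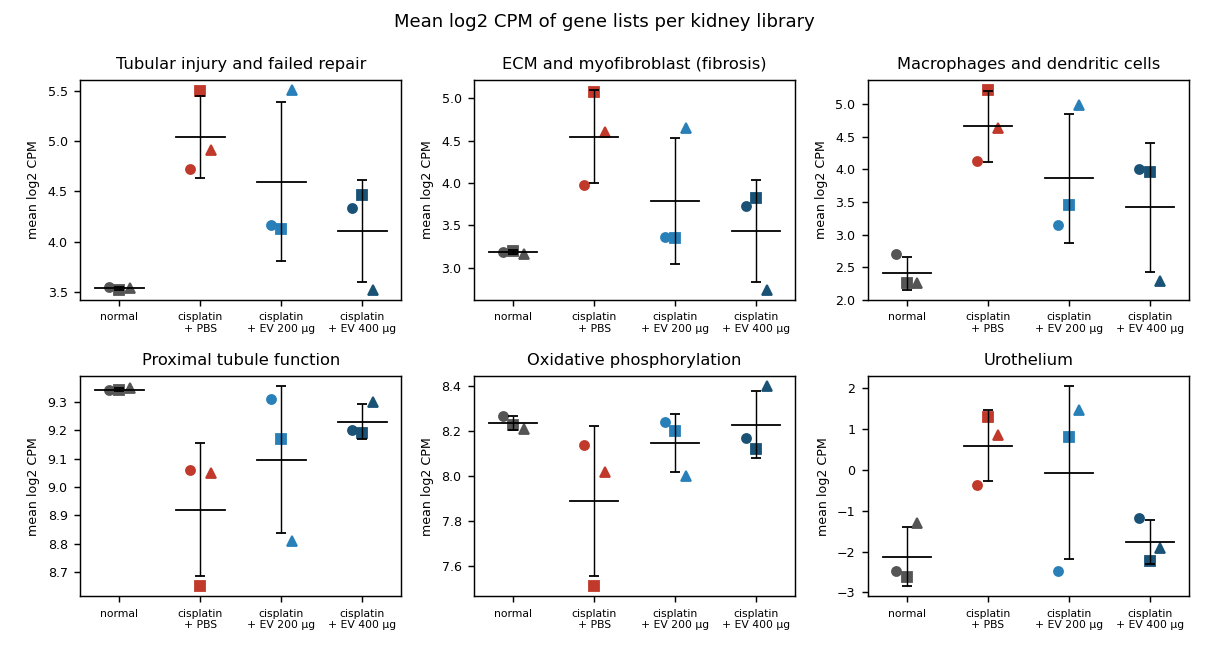
Mean log2 CPM over the members of 6 gene lists in each kidney library. Points are libraries with the shape naming the replicate, black lines are group means and bars are 1 SD (n = 3). Tubular injury averages 3.54 in normal and 5.04 in PBS, and EV200 3 stands at 5.51, close to PBS 2 at 5.5.

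The comparison of EV200 with PBS asks what the lower vesicle dose changed in cisplatin-treated kidneys. A single gene other than provisional models was called: Aak1 (chromosome 6, 86849274 to 87003227), which encodes a kinase of clathrin-mediated endocytosis, rose 2.53-fold from 37.07 ± 10.4 to 93.83 ± 6.17 CPM. Its Benjamini-Hochberg adjusted p by edgeR was 0.0202. The provisional gene model Gm38495 fell from 54.61 ± 16.2 to 0.3221 ± 0.285 CPM, and LOC115488616 fell from 0.4493 ± 0.0873 CPM to a count of 0 in each EV200 library. Gm38495 was named by the part of the rule on opposite calls. LOC115488616 lies outside the naming rule and was chosen after its values were seen. The RefSeq table gives Gm38495 as an older name of Aak1. Summed over both, the PBS libraries had 87.2, 98.4 and 89.4 CPM and the EV200 libraries 93.5, 101 and 88.1 CPM. These ranges overlap, so the rise of Aak1 alone does not show a rise of the pair.

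The test called 3 genes, 1 up and 2 down, with 1293 at an unadjusted p under 0.05, 48 by DESeq2 and 1649 by limma-voom. Fitting only the groups compared gave 0, while the summed counts of Aak1 and Gm38495 gave 1 and the clock score 0. The count was 6 without PBS 3, 1 without EV200 1 or EV200 2, 2 without PBS 2 or EV200 3, and Aak1 missed the threshold without PBS 3, EV200 1, EV200 2 or EV200 3, with adjusted p of 0.0513, 0.115, 0.205 and 0.0505 by edgeR with Benjamini-Hochberg adjustment. None of the 12 injury and fibrosis genes passed, over all genes or adjusted over the list alone, by edgeR. None of them had an unadjusted p under 0.05, DESeq2 called 0, with no adjusted p for Lcn2, and limma-voom 8. Havcr1 averaged 10.43 ± 13.5 CPM in EV200, with 3.77 and 1.51 CPM in EV200 1 and EV200 2 and 26 CPM in EV200 3. Log2 fold changes against PBS were 0.12 (SE 0.79) for Havcr1, -0.31 (SE 0.83) for Lcn2, -1.13 (SE 0.56) for Col1a1, -0.99 (SE 0.56) for Col3a1, -0.86 (SE 0.49) for Fn1 and -0.59 (SE 0.39) for Cdkn1a. They were -0.45 for Vcam1, -0.46 for Krt20, -0.32 for Acta2, -0.39 for Tgfb1, -0.35 for Ccl2 and 0.18 for Umod. Limma-voom gave PBS 2 and EV200 3 low quality weights of 0.163 and 0.283, and PBS 3 and EV200 2 high ones of 3.47 and 2.97. Its values therefore lean on PBS 3 and EV200 2. Limma-voom turned Havcr1 to -1.40 (SE 0.47). It had -1.09 for Lcn2, -1.57 for Col3a1, -1.43 for Vcam1, -2.63 for Krt20, -0.62 for Acta2, -1.97 for Ccl2 and 0.12 for Umod, while DESeq2 had 0.13 for Havcr1. The size of these changes, and for Havcr1 the direction, therefore depends on the tool.

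Camera called 18 lists between EV200 and PBS, 8 up and 10 down, and neither the estimated correlation (smallest adjusted p 0.126) nor fry called any. Of the 645 list genes, edgeR called 0 over all genes, with 61 at an unadjusted p under 0.05, 12 called by DESeq2 and 123 by limma-voom. The fibrosis list was lower with a mean of -0.69, and no member passed adjusted over the list alone (adjusted p = 0.688 with an estimated correlation). The macrophage list was lower by a mean of -0.62 and the oxidative phosphorylation list higher by 0.23, with no member past the test adjusted over the list alone (adjusted p = 0.688 with an estimated correlation for each). The erythroid list was higher by a mean of 0.69, with 6 of 8 members up adjusted over the list alone (adjusted p = 0.126 with an estimated correlation). Circadian clock genes were higher by 0.26, with 9 up and 3 down of 18 adjusted over the list alone (adjusted p = 0.126 with an estimated correlation). The tubular injury list had a mean of -0.28 (adjusted p = 0.732 with an estimated correlation), and camera did not call it without PBS 2, EV200 1 or EV200 2, where Benjamini-Hochberg adjusted p was 0.661, 0.536 and 0.627. Without EV200 3 the means were further from 0, at -0.98 for tubular injury, -1.41 for fibrosis and -1.44 for macrophages. Without PBS 2 they were 0.03, -0.37 and -0.285, and for oxidative phosphorylation 0.07 (0.36 without PBS 1). Without EV200 1 and without EV200 2, macrophages had -0.31 and -0.37. The number of lists called was 7 without PBS 2, 10 without EV200 1 and 12 without EV200 2, with 6, 9 and 11 of these among the 18.

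The comparison of EV400 with PBS asks the same of the higher dose. Core clock genes made up 5 of the 15 called genes. With no hour of collection in the labels, their shift cannot be told apart from a different collection time. Arntl, encoding the clock activator BMAL1 (chromosome 7, 113178471 to 113314126), fell from 11.33 ± 4.47 to 1.946 ± 0.707 CPM, and Npas2, encoding a partner of BMAL1, fell from 9.207 ± 4.14 to 1.747 ± 0.579 CPM. Ciart (chromosome 3, 95878500 to 95882257), a repressor of the clock activators, rose 5.46-fold to 13.53 ± 3.21 CPM, and the clock repressor genes Per3 and Cry2 rose 2.07-fold and 1.95-fold. Ren1, encoding renin (chromosome 1, 133350674 to 133360320), rose 2.55-fold from 22.54 ± 3.74 to 57.38 ± 7.48 CPM, above the normal level of 34.17 ± 4.54 CPM. The adjusted p of these genes by edgeR with Benjamini-Hochberg adjustment ran from 0.0336 to 0.0493. Arntl and Dbp in EV400 lay past the normal level too, with Arntl at 1.16 to 2.53 CPM against 3.18 to 3.27 in normal and Dbp at a mean of 115 against 87.2 CPM, though edgeR called 0 genes between these groups.

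The test called 15 genes, 9 up and 6 down, with 4403 at an unadjusted p under 0.05, 1004 by DESeq2 and 2731 by limma-voom, both of which included all 15. Fitting only the groups compared gave 2, of which 1 was among the 15, while summing the counts of Aak1 and Gm38495 gave 6 and a clock score as covariate 0, both chosen after seeing the data. The count was 1 without PBS 1, PBS 2 or EV400 3, 0 without EV400 1 or EV400 2, and 26 without PBS 3. Also called up were Aak1 at 1.30, Nat8f5 at 1.25, and Fmo2, encoding a flavin-containing monooxygenase, at 0.59, with Gm10384 at 2.71 and Trdn, encoding the calcium release protein triadin, at 1.86. Summed over Aak1 and Gm38495, the EV400 libraries had 88.6, 102 and 84.6 CPM, overlapping the PBS libraries at 87.2, 98.4 and 89.4 CPM. Called down were Banp, encoding a matrix-binding nuclear protein, at -1.22, Ypel2 at -1.11, the monocarboxylate transporter gene Slc16a1 at -0.96, and Gm38495 at -7.40. Gm10384 and Gm38495 were named by the part of the rule on opposite calls. Trdn lies outside the naming rule and was chosen after its values were seen.

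None of the 12 injury and fibrosis genes passed over all genes in EV400 against PBS, and 3 passed adjusted over the list alone. By edgeR 7 had an unadjusted p under 0.05, DESeq2 called 1, with no adjusted p for Lcn2 and Krt20, and limma-voom 6. In 7 of the 12, each EV400 library lay below each PBS library, and chance parts the groups in one direction or the other for 10% of genes. Havcr1 averaged 2.226 ± 1.33 CPM in EV400, a log2 fold change of -2.10 (SE 0.85) against PBS, with a Benjamini-Hochberg adjusted p of 0.185 by edgeR. Values were -1.95 (SE 0.87) for Lcn2, -1.76 (SE 0.58) for Col1a1, -1.73 (SE 0.57) for Col3a1, -1.30 (SE 0.50) for Fn1 and -1.17 (SE 0.40) for Cdkn1a. Those of Vcam1, Krt20, Acta2, Tgfb1, Ccl2 and Umod were -1.47, -1.44, -0.55, -0.53, -1.45 and -0.02. Limma-voom weighted EV400 3 by 0.344 and PBS 2 by 0.163, but EV400 1 by 3.38 and PBS 3 by 3.47. It had -1.02 for Lcn2, -0.85 for Vcam1, -0.56 for Cdkn1a and -0.05 for Umod, and DESeq2 had -1.95, -1.47, -1.17 and -0.02. Adjusted p over all 12 ran from 0.157 to 0.931 by edgeR with Benjamini-Hochberg adjustment.

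**Figure D3:**
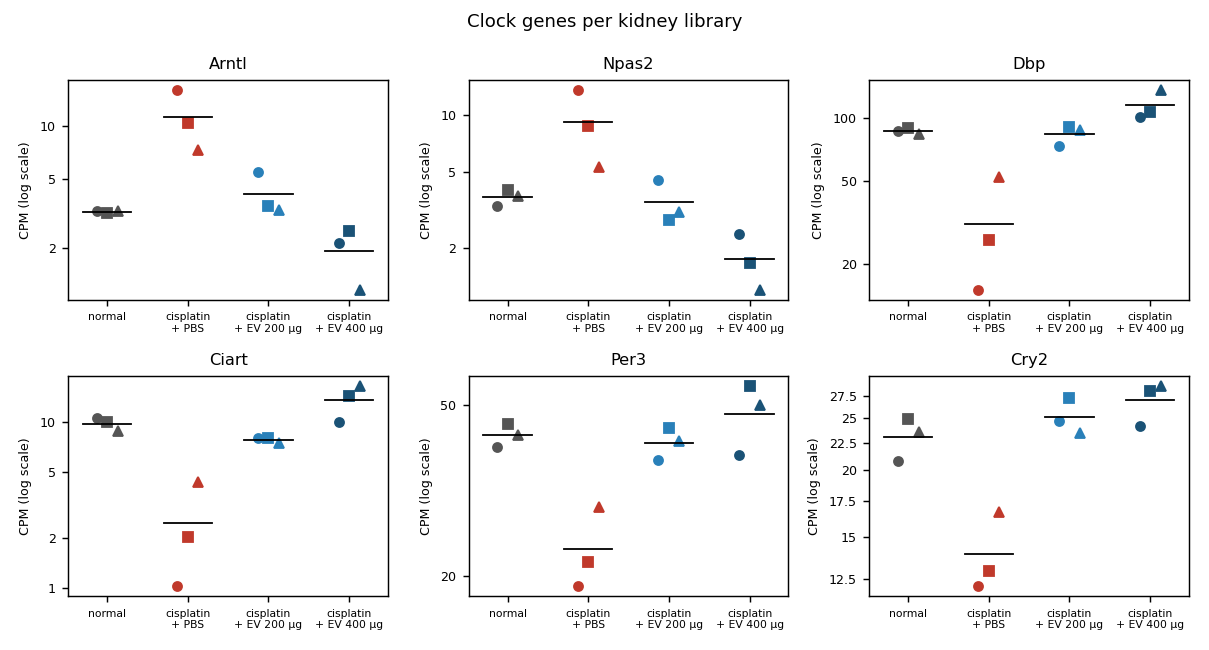
CPM on a log axis for 6 circadian clock genes in the 12 kidney libraries. Each point is a library, its shape names the replicate number, and the black line is the mean of the group. Arntl lies at 7.33 to 16.2 CPM in PBS and at 1.16 to 5.5 CPM in all other libraries.

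Camera called 19 lists between EV400 and PBS, 8 up and 11 down. None was called with an estimated correlation, where the smallest adjusted p was 0.266, and fry called 4. The fibrosis list was lower with a mean of -1.11, and 14 of 30 members fell adjusted over the list alone while 0 did over all genes (adjusted p = 0.455 with an estimated correlation). The tubular injury list had a mean of -0.92 with 6 of 29 down adjusted over the list alone and 0 over all genes, and the urothelial list -2.56 with 7 of 12 down and 0 (adjusted p = 0.455 with an estimated correlation for each). The proximal tubule list was higher by 0.29, with 11 of 39 up adjusted over the list alone and 0 over all genes (adjusted p = 0.455 with an estimated correlation). Macrophage genes had a mean of -1.08 and oxidative phosphorylation genes 0.32, with no member past the test adjusted over the list alone (adjusted p = 0.455 with an estimated correlation for each). In the circadian list 3 members rose and 2 fell over all genes, and 9 rose and 3 fell adjusted over the list alone (adjusted p = 0.266 with an estimated correlation). Library EV400 3 had lower scores than EV400 1 and EV400 2, at 2.74 against 3.73 and 3.82 for fibrosis and 2.28 against 4.01 and 3.96 for macrophages, and without it the means were -0.87 and -0.74. Without PBS 2, proximal tubule genes had 0.17 and oxidative phosphorylation genes 0.16. Of the 645 list genes, 5 passed edgeR's test over all genes, 235 had an unadjusted p under 0.05, and DESeq2 and limma-voom called 76 and 151.

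The doses were also compared directly. Between EV400 and EV200, edgeR's test called 1 gene, the provisional model LOC115488616, with 1187 at an unadjusted p under 0.05, 17 by DESeq2 and 145 by limma-voom. It lay at 0.519 ± 0.0538 CPM in EV400, at least 9.95-fold higher than EV200 against a floor of 3 counts per library. This gene was chosen after its values were seen. None of the 12 injury and fibrosis genes passed over all genes or adjusted over the list alone, with 1 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Havcr1 had -2.22 (SE 0.85) and Lcn2 -1.64 (SE 0.87), with Benjamini-Hochberg adjusted p of 0.769 for both by edgeR. The Havcr1 value rests largely on library EV200 3, where its level, given above, was far higher than in the other libraries of that group. Camera called 14 lists, 4 up and 10 down, and none with an estimated correlation (smallest adjusted p 0.414). It called 7 without EV200 3, of which 4 were among the 14, and 9 without EV400 3, of which 8 were.

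Against normal, the EV200 kidneys had 13 called genes, 6 up and 7 down. St14, encoding the epithelial protease matriptase, rose from 31.61 ± 0.965 to 53.1 ± 7.08 CPM, and the homeobox gene Irx2, the kinase gene Stk32b and the retinoid transporter gene Abca4 rose by 0.86, 0.73 and 0.70. Synpr changed by -4.51, Ctxn3 by -1.74, Srd5a2 by -1.31 and Coro2a by -0.87. Their adjusted p ran from 0.00446 to 0.0408 by edgeR with Benjamini-Hochberg adjustment, and the test had 2469 genes at an unadjusted p under 0.05, with 491 by DESeq2 and 1098 by limma-voom. The count was 2 without normal 1 or normal 2, 4 without normal 3 or EV200 2, 8 without EV200 3 and 58 without EV200 1. The loop of Henle list was higher by 0.55 and was the 1 list of 18 called that held with an estimated correlation (adjusted p = 0.0259 with an estimated correlation), with 9 of 12 members up adjusted over the list alone and 0 over all genes. Of the 12 injury and fibrosis genes 0 passed over all genes and 7 adjusted over the list alone, with 7 at an unadjusted p under 0.05, 3 by DESeq2 and 1 by limma-voom.

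Between the EV400 and normal groups edgeR called 0 genes, and its smallest Benjamini-Hochberg adjusted p was 0.176. At an unadjusted p under 0.05 there were 1308 genes, and DESeq2 called 35 and limma-voom 1481. Lcn2 averaged 3.194 ± 2.29 CPM, a log2 fold change of 2.57 (SE 1.01), and Havcr1 0.54 (SE 0.88). None of the 12 injury and fibrosis genes passed over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05, 0 by DESeq2 and 2 by limma-voom. Camera called 11 lists, 8 up and 3 down, with macrophages at a mean of 1.25 and tubular injury at 0.67 (adjusted p = 0.825 with an estimated correlation for each). None of the 11 was called with an estimated correlation, and 7 lists were called without EV400 1, all among the 11. A missed threshold does not show that these kidneys matched normal ones.

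The mean of both doses against PBS gave 7 called genes, 2 up and 5 down, with 3625 at an unadjusted p under 0.05, 381 by DESeq2 and 3543 by limma-voom. Fitting only the groups compared gave 1 and the clock score as covariate 0. The count was 2 without PBS 1, PBS 2, EV400 2 or EV400 3, 1 without EV200 2, 4 without EV400 1, 18 without PBS 3 and 17 without EV200 3. Over the 4 groups, 12 genes differed in some way, with 3696 at an unadjusted p under 0.05, 1726 by DESeq2 and 6634 by limma-voom. That count fell to 1 without normal 1, normal 2, normal 3 or EV200 2, and to 7 without PBS 1 or PBS 2. It was 27 without PBS 3, 19 without EV200 1 and 409 without EV200 3. Camera called 22 lists for the mean of both doses, 9 up and 13 down, and none with an estimated correlation (smallest adjusted p 0.184).

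Genes called in PBS against normal were compared with those called for each dose against PBS, to find genes called in opposite directions. EV400 shared 11 such genes, 3 up with cisplatin and down with EV400 and 8 the other way, where independent lists would share 0.111 and 0.0812. The clock genes Arntl, Ciart, Per3 and Cry2 were among them, with Nat8f5, Fmo2, Ypel2, Trdn, Aak1, Gm10384 and Gm38495, and none went the same way in both. For the clock genes, an effect of treatment cannot be told apart from collection time, since the labels give no hour. EV200 shared 2, Aak1 and Gm38495, a symbol the RefSeq table gives as an older name of Aak1. With their counts summed, 0 were shared with EV200 and 5 with EV400. Of the 514 genes called with cisplatin, 98.8% had a log2 fold change of opposite sign in EV400 and 92.4% in EV200. Both comparisons use the same PBS libraries. In 20 simulated runs the vesicle groups had the PBS means, while the difference of PBS from normal was kept, and these gave 64.8% and 65.1%.

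Across genes, which are not independent replicates, the log2 fold changes of cisplatin and EV400 had r = -0.719 and a covariance of -0.372, against -0.192 and -0.0683 in the simulation. For EV200 they were -0.595 and -0.218 against -0.198 and -0.0698. Between the doses, 2 genes were called in the same direction, with r = 0.635 and a covariance of 0.167, against 0.494 and 0.0711 when simulated. Independent lists would share 0.000481 genes up and 0.000641 down. The simulation draws genes independently, and the 3 PBS libraries are too few to be split, so part of each excess may come from the shared controls. The 11 shared genes fell to 0 without normal 1, normal 2, normal 3, EV400 1 or EV400 2 and to 1 without PBS 1, PBS 2 or EV400 3, and rose to 18 without PBS 3. The 2 shared with EV200 became 0 without normal 1, normal 2, normal 3, EV200 1 or EV200 2, 1 without PBS 2 or EV200 3, and 5 without PBS 3.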

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

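The comparison of the doses was planned, and the tests of library EV200 3 were chosen only after its values were seen. What brought the following results here is a difference between the vesicle doses by its own test, EV400 against EV200. The provisional gene model LOC115488616 differed, with a count of 0 in each EV200 library. It was at least 9.95-fold higher in EV400 against a floor of 3 counts per library, and its fitted log2 fold change of 7.79 depends on the prior count and is no bound. Gene lists lower in EV400 than in EV200, as means of log2 fold changes, were fibrosis at -0.42, TGF-beta signalling at -0.26, tubular injury at -0.65, loop of Henle at -0.22 and endothelium at -0.12. Lower as well were macrophages and dendritic cells at -0.46, interferon response at -0.31, cell cycle at -0.38, immediate early and heat shock genes at -0.45 and urothelium at -2.48. Higher in EV400 were proximal tubule function at 0.11, fatty acid oxidation at 0.05, oxidative phosphorylation at 0.08 and androgen-responsive genes at 0.2. None of the 14 lists was called with an estimated correlation, where the smallest adjusted p by camera with Benjamini-Hochberg adjustment was 0.414. Without EV200 3, 7 lists were called, of which 4 were among the 14 and 3 were other lists. The means of fibrosis and macrophages then turned to 0.302 and 0.357, and tubular injury, TGF-beta signalling and cell cycle had 0.056, 0.007 and 0.003 and were no longer called. Also no longer called were proximal tubule, endothelium, interferon response, fatty acid oxidation and oxidative phosphorylation lists, at -0.025, -0.078, -0.053, 0.018 and 0.013. Immediate early and heat shock genes had -0.063 and androgen-responsive genes 0.114, both still called. Without EV400 3, 9 lists were called, 8 of them among the 14. No longer called then were fibrosis at -0.186, macrophages at -0.131, TGF-beta signalling at -0.152, endothelium at -0.049, fatty acid oxidation at -0.012 and oxidative phosphorylation at -0.003, while proximal tubule and androgen-responsive genes had 0.073 and 0.114. Endothelium missed the threshold without EV200 1 too, at -0.107, and TGF-beta signalling without EV400 2, at -0.32. Other omissions widened differences that stayed called. Without EV200 1, proximal tubule, oxidative phosphorylation and macrophage lists had 0.23, 0.135 and -0.764, and without EV200 2, fibrosis, macrophage and fatty acid oxidation lists had -0.636, -0.701 and 0.085. Without EV400 2, fatty acid oxidation and oxidative phosphorylation had 0.122 and 0.14, and without EV400 1, macrophages had -0.699 but fatty acid oxidation 0.031. Most of these differences between doses therefore depend on library EV200 3, and many on EV400 3 as well.

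Library EV200 3 had injury levels like the PBS group, with a tubular injury score of 5.51 against 4.16 and 4.12 in EV200 1 and EV200 2. A label swapped with a PBS library was checked on the clock score and on Gm38495. EV200 3 had a clock score of 0.37, outside the PBS range of -3.98 to -1.16, and 0 CPM of Gm38495. No PBS library had EV200 values of either. Both measures were chosen after they were seen to set the labelled PBS libraries apart, so they cannot decide on a swap. PBS 1 had the lowest tubular injury score of its group, 4.72. Regrouping with PBS 2, PBS 3 and EV200 3 set apart called 1768 genes, against 3 for the labelled groups. A swap therefore stays open. A lower share of proximal tubule RNA alone would raise other cell types together. Their medians moved apart, from -0.65 (SE 0.12) in the distal tubule list to 1.6 (SE 0.1) for macrophages and 2.17 (SE 0.25) for urothelium. Each SE is that of the mean over the genes of a list, which are not independent, and does not measure the spread between libraries. The medians therefore speak against that explanation without excluding it. A real difference in injury between animals stays open, and no biological explanation was tested.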

How the results depend on the processing

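The clock score covariate, the summed gene models, the omission of PBS 3 and EV200 3, and fry were chosen only after the results were seen. Counts of called genes follow in the order PBS against normal, EV200 against PBS, EV400 against PBS, EV400 against EV200, EV200 against normal, EV400 against normal, mean of doses, any difference, and opposite calls with EV200 and EV400. DESeq2 gave 2855, 48, 1004, 17, 491, 35, 381, 1726, 38 and 593. Limma-voom with quality weights gave 6164, 1649, 2731, 145, 1098, 1481, 3543, 6634, 1242 and 1754. Its weights ran from 0.163 for PBS 2 to 3.47 for PBS 3. Within the vesicle groups EV200 2 and EV400 1 weighed most, at 2.97 and 3.38, so these counts lean on single libraries. Leaving out 1 library gave ranges of 0 to 2277, 1 to 6, 0 to 26, 1 to 1, 2 to 58, 0 to 0, 1 to 18, 1 to 409, 0 to 5 and 0 to 18, and lists called ran from 20 to 23, 7 to 23, 18 to 24, 7 to 16, 12 to 18, 7 to 16 and 16 to 25 in the first 7. Without PBS 3 and EV200 3 the counts were 1691, 6, 97, 0, 6, 1, 60, 68, 5 and 89, and 7 lists were called for EV400 against EV200 and 11 for EV200 against normal. With the clock score as covariate they were 0, 0, 0, 0 and 6 for the first 5, and 0 for the mean of doses, for any difference and for opposite calls with EV200 and with EV400. Fitting only the groups compared gave 1449, 0, 2, 0, 28 for the first 5 and 1 for the mean of doses.

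With at least 1 CPM in 3 samples, counts were 819 for PBS against normal, 0 for EV400 against EV200 and 26 for EV200 against normal, and without a low-count filter the first was 299. Requiring an absolute log2 fold change of 1 left 239, 4 and 7 for PBS against normal, EV200 against normal and any difference. Summing Aak1 and Gm38495 left 1 gene for EV200 against PBS, 6 for EV400 against PBS, and 0 and 5 opposite calls with EV200 and EV400. Replicate number as a block gave 0 for PBS against normal, EV200 against PBS, EV400 against EV200, any difference and opposite calls with EV200 and EV400, and 6 for EV200 against normal. Only 2 of 18 same-numbered pairs had r above 0.1 (range -0.385 to 0.344), so the numbers do not pair the samples. Other counts stayed within 1.5 times, including all those with the scaling factors of DESeq2. The unit alternative concerned FPKM or TPM values and was not run. An estimated correlation left 0, 0, 0, 0, 1, 0 and 0 lists called in the first 7 comparisons, and fry 11, 0, 4, 0, 2, 0 and 2. Leaving libraries out also leaves fewer samples, and the cause of these moves was not tested.

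With the clock score as covariate, which the PBS group largely sets, the direction of some tests reversed. The fatty acid oxidation list went to 0.109 for PBS against normal, -0.138 for EV200, -0.229 for EV400 and -0.183 for the mean of doses against PBS and -0.091 for EV400 against EV200, tubular injury to 0.02 for EV200 and the circadian list to -0.02 for EV400. Dbp went to 0.1 for PBS against normal, and Ciart, Per3 and Npas2 to -0.15, -0.03 and 0.02 for EV400 against PBS. These genes are part of the score, and the circadian list shares genes with it. Their values near 0 therefore follow from how the score was made and test nothing. Leaving out 1 library, EV400 against EV200 ran from -0.636 to 0.302 for fibrosis and from -0.764 to 0.357 for macrophages, and cell cycle in EV200 against normal from -0.067 to 0.486. Without PBS 3 and EV200 3 these had 0.13, 0.356 and -0.052. The cause of the other moves was not tested. Among values of named genes, leaving out 1 library ended 376 calls and added 32, and DESeq2 added 79. Status was unchanged in 1344 and 198 values, which include genes called in neither fit, so these are not counts of calls kept. Leaving out 1 library kept 688 list calls, ended 106 and reversed the direction of camera's test in 4, of 798. The sign of a list's mean turned in 17 of the 798, 1 of them still called. Among these were the adrenal list in EV400 against normal, from 0.61 to -0.04, -0.036 and -0.906 without normal 2, normal 3 and EV400 2, and those given above for EV400 against EV200. Depth limits genes of few counts: a count of 0 in 3 libraries leaves levels below the floor of 3 counts per library open.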

Other observations

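All tests in this part were chosen only after the results were seen, except that of exons shared by Aak1 and Gm38495. Regrouping the libraries gives 10 splits for each pair of groups, too few for a share under 0.05. For called genes, the number of splits reaching the real count, the real count and the highest other were 1, 514 and 0 for PBS against normal, 2, 3 and 1768 for EV200 against PBS, and 1, 15 and 1 for EV400 against PBS. They were 2, 1 and 1 for EV400 against EV200, 1, 13 and 1 for EV200 against normal, and 10, 0 and 0 for EV400 against normal. For lists they were 4, 20 and 23 for PBS against normal, 5, 18 and 27 for EV200 against PBS, and 3, 19 and 22 for EV400 against PBS. They were 7, 14 and 21 for EV400 against EV200, 4, 18 and 19 for EV200 against normal, and 3, 11 and 18 for EV400 against normal.

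Where more than 100 splits exist, 100 were drawn with the real one among them. For the mean of both doses against PBS, 4 of 100 reached the real 7 genes and the highest other called 3987. For any difference these were 4 of 100, 12 and 2130. For the mean of doses, every other draw that reached 7 had PBS 2, PBS 3 and EV200 3 as the PBS group. That share therefore counts draws, not distinct choices of the PBS group. Both shares are under 0.05, but so near it that a draw of 100 does not firmly exclude chance. It cannot be excluded for lists called for the mean of both doses (17 of 100, real 22, highest other 28), for opposite calls with EV200 (7 of 100, real 2, highest other 938), or with EV400 (5 of 100, real 11, highest other 3359). Nor can it for the covariance of cisplatin and vesicle fold changes, where 5 of 84 regroupings were as low as the real -0.2413 and the lowest other was -0.3738. For opposite calls, draws reaching the real count include some with the real PBS group, which redraw only the vesicle libraries. Others share the set PBS 2, PBS 3 and EV200 3 as the PBS group. The shares thus count draws, not distinct choices of that group. Splits calling many times the real count point to a structure of the samples: the split of EV200 and PBS that called 1768 genes set PBS 2, PBS 3 and EV200 3 apart from the rest.

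Aak1 was low and Gm38495 high in the PBS group alone. The summed counts of both changed by -0.14 (SE 0.09, 95% interval -0.34 to 0.06) between PBS and normal, against -1.44 (-1.82 to -1.06) for Aak1 alone, which is consistent with reads divided differently between both gene models. The RefSeq table gives Gm38495 as an older name of Aak1. Exons shared by the models as counted could not be looked up, since only 1 of the pair is in GENCODE vM21. Whether such all-or-none genes fall on a group by chance is open too, as 5 of 9 settings gave a binomial p under 0.05 (p from 0.000655 to 0.244). The value of Aak1 alone may therefore not measure the gene's total output.

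Clock genes were shifted in the PBS group, and in EV400 clock scores lay past normal the other way, at 1.21 to 2.63 against 0.3 to 0.67, while edgeR called 0 genes between EV400 and normal. Injury severity within groups does not decide it: over 9 cisplatin libraries centred by group, injury and clock scores had r = -0.145 (exact permutation p 0.681, 216 permutations), rho = -0.2 (p 0.63) and r = -0.164 without PBS 2 and EV200 3. A different collection time of the PBS animals, of the EV400 animals or of both cannot be told apart from an effect of treatment, because the highest PBS clock score was -1.16, the lowest in any other group was -0.06, the lowest in EV400 was 1.21, and the labels give no hour. An effect of the vesicles or of cisplatin on the clock stays open as untested.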
